A study of Homo sapiens with 12 samples.

How the data were processed

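RNA of RPE1 cells was sequenced in 12 libraries, 4 per group: control (DMSO), doxorubicin, and doxorubicin with ferrostatin-1. Per the labels, libraries were made with a kit that does not mark the strand and were read from both ends, and selection of poly(A) RNA is not stated. The deposited table holds counts per gene, and the values look like counts: they are whole numbers and sum to a different total in every library. Whether they had been adjusted for gene length before becoming whole numbers was not tested. The submitters' processing notes name Salmon, DESeq2 and the genome build GRCh38, without versions and without saying which step each tool served. How fractional counts became whole numbers and which annotation release gave the identifiers are not stated either. Library totals ran from 17523920 counts upward, and intervals and limits from them cover counting error only, since reads were not marked by molecule.

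Count columns carry a group name and a number from 1 to 4, and 0 count columns were left without a group. Sample titles are numbered from 1 to 12 within the same groups, so each column's group is known, but which title a column belongs to rests on their order alone and no result uses it. Nothing in the labels pairs replicate 1 of one group with replicate 1 of another. Residuals of libraries with the same number correlated at r = -0.0954 to 0.0534 in 12 pairs, and those with different numbers at -0.146 to 0.154 in 36 pairs, so no block was used. Labels speak of 4 replicates and nothing more, so the tests cover variation between the 4 replicates of a group in this 1 line, and whether those were separate cultures or days is not stated.

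Gene symbols came from the deposited table, which lacks one for 1935 identifiers and gives 618 symbols to more than one identifier. For those, the lists used the identifier with the most counts. Biotype and position came from GENCODE 29 on GRCh38, matched by identifier without its version for 20832 of 22498 identifiers (92.6%), and the remainder has no position here. Protein-coding genes took 96.5% of the counts. A side column of the same table holds 71 gene symbols with no stated purpose, described as a list of its own.

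Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 13803. Libraries were scaled by TMM factors. One edgeR quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, and 3 contrasts were tested: doxorubicin against control, both compounds against doxorubicin, and both compounds against control. P-values are two-sided and adjusted by Benjamini-Hochberg over all tested genes within a contrast, and a gene was called at an adjusted p below 0.05. Adjusted p-values with n = 4 all come from this model unless another tool is named. Log CPM for correlations and principal components used a prior count of 2. All code ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.

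Before the data were examined, 36 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The lists used here are G2/M and mitosis, DNA replication, replication-dependent histones, DNA repair, SASP factors, NF-kB targets, interferon-stimulated genes, ferroptosis defence, ferroptosis-promoting lipid and oxidase genes, iron handling, NRF2 targets, ATF4 targets, unfolded protein response, cholesterol synthesis, fatty acid synthesis, aryl hydrocarbon receptor targets, metallothioneins and zinc export, hypoxia response, mitochondrially encoded genes, nuclear oxidative phosphorylation, cytosolic ribosomal proteins, lysosome, extracellular matrix, TGF-beta targets, YAP/TAZ targets, actin cytoskeleton, senescence markers, apoptosis, immediate early genes, heat shock, retinal pigment epithelium markers, epithelial markers, and markers of immune, endothelial and neuronal cells. Of the 36, 1 list and single genes of others are not reported here, though totals over lists and genes include them. They were written from general knowledge and do not come from a database. Lists with at least 5 tested members were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera was repeated with a correlation estimated for each list, and fry asked whether a list's genes moved one way on balance.

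The naming rule picked, for each contrast, the 8 protein-coding genes with the largest rise and the 8 with the largest fall among called genes with a symbol, a mean log2 CPM of at least 1 and all 4 libraries of one group above all 4 of the other. It added up to 4 members with the smallest p-values of each called list and of lists fixed beforehand, among them the ferroptosis, iron, NRF2 and SASP lists. It added 16 anchor genes in every contrast, of which 15 were tested. It also added the 6 genes with the largest opposite changes in the doxorubicin and ferrostatin-1 contrasts. Not all of these are named in the text. Genes named from outside the rule are said to have been chosen after their values were seen.

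Alternatives were DESeq2 and limma-voom, RLE and upper quartile factors and library totals in place of TMM, other filters on low counts, protein-coding genes alone, fits of only the groups compared, stricter thresholds, leaving out each library in turn, and doxorubicin libraries split between contrasts. A block from the numbers in the column names, counts summed over identifiers with the same symbol, and the list from the side column were added after seeing the data. The model was tested on simulated data with the totals and spread of these libraries and 50 changed genes per fold among 13803. It called 70% of genes changed 2-fold in the doxorubicin contrast, 82% in the ferrostatin-1 contrast and 88% in the contrast of both compounds with control, with 8, 8 and 5 false calls. Of genes changed 1.25-fold it called 38%, 30% and 50%, so genes that did not pass may have changed by that much. In the data many more genes were called, 64.0% for doxorubicin and 64.3% for both compounds against control. The adjustment is then less strict, so the simulated shares may be too low for these contrasts.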

Results

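RNA was sequenced from RPE1 cells, an immortalised human retinal pigment epithelial line, in 12 libraries that fell into 3 groups of 4. The control group received the solvent DMSO. The second group received 50 nM doxorubicin, an anthracycline that traps topoisomerase II on DNA and breaks it. The third group received 50 nM doxorubicin together with 5 µM ferrostatin-1, a radical-trapping compound that stops lipid peroxidation and thereby ferroptosis, an iron-dependent form of cell death. Treatment lasted 72 h, and ferrostatin-1 was added again at 48 h. No group received ferrostatin-1 without doxorubicin, so its effect was measured in doxorubicin-treated cells only. Total counts ran from 17523920 to 19650696 per control library, from 17980433 to 20607019 per doxorubicin library and from 20243458 to 24879198 per library with both compounds.

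Of 22498 gene identifiers in the table, 13803 had enough counts to be tested. Levels are TMM-scaled CPM, counts relative to the library's size, given as mean ± SD with n = 4. Log2 fold changes are given ± a standard error derived from the edgeR test. It is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. A count of 0 allowed a level of up to 0.121 to 0.171 CPM, depending on the library. The mitochondrial genome supplied 2.91% ± 0.123 (SD, n = 4) of the counts in control libraries, 3.97% ± 0.0861 in doxorubicin libraries and 3.74% ± 0.216 with both compounds. Across genes, the log2 CPM of 2 libraries correlated at r = 0.977 to 0.982 within a group and at 0.924 to 0.979 between groups. Control replicate 1 stood apart from 2 others of its group, with a chi-square per degree of freedom over genes of 12.3 and 14.2 against control replicates 3 and 4. Among control replicates 2 to 4 it was 3.73 to 5.03, and the closest pair from different groups had 10.1. Without that library, doxorubicin changed 8660 genes and ferrostatin-1 786, against 8833 and 692 with it. Principal component 1, with 57.6% of the variance, separated the 4 control libraries from the 8 treated ones. Principal component 2, with 6.68%, separated the 4 doxorubicin libraries from the 4 that also received ferrostatin-1.

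**Figure D1:**
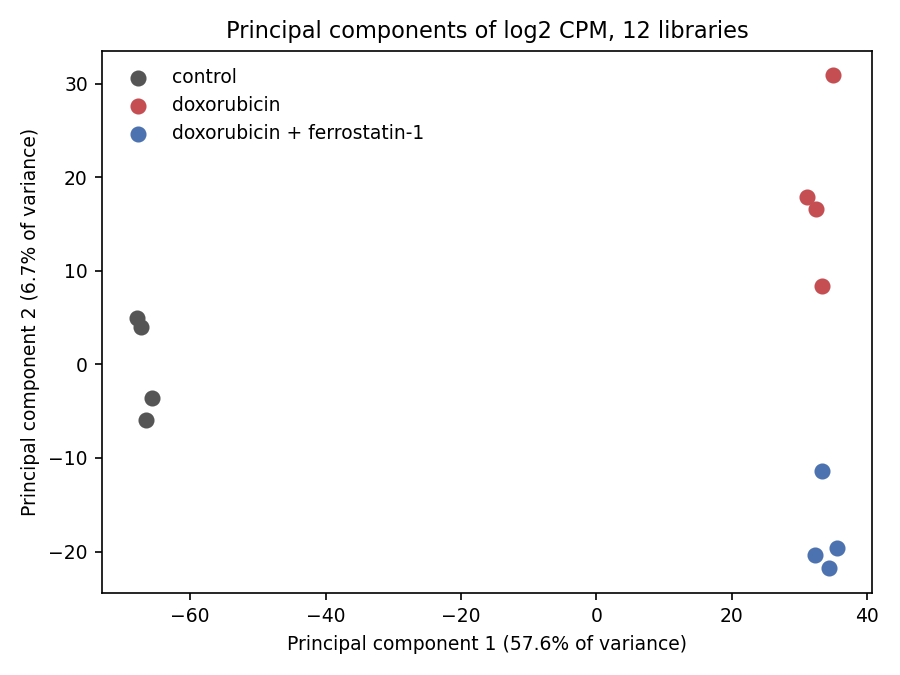
Principal components 1 and 2 of log2 CPM, 1 point per library, coloured by group. Component 1 (57.6% of the variance) parts control from treated libraries, and component 2 (6.68%) parts doxorubicin libraries from those that also received ferrostatin-1.

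The comparison of doxorubicin with control asked how 72 h of the drug changed the cells. Genes of cell division fell together, and the cell-cycle inhibitor gene CDKN1A rose. MKI67, the proliferation marker Ki-67, fell from 754 ± 120 to 31.3 ± 4.03 CPM (log2 fold change -4.59 ± 0.13, adjusted p = 4.79e-13). CDKN1A, which codes for the cell-cycle inhibitor p21 (ENSG00000124762.14, chromosome 6 from 36676460 to 36687339, GRCh38, GENCODE 29), rose from 191 ± 9.91 to 1508 ± 55.7 CPM (2.98 ± 0.044, adjusted p = 6.45e-16). LMNB1, a nuclear lamina gene lost in senescent cells, fell from 180 ± 5.42 to 8.14 ± 1.28 CPM (-4.46 ± 0.099, adjusted p = 2.84e-14). Lists of secreted factors, contractile proteins and lysosomes rose as well, and so did those of histones and matrix, whose calls were lost with an estimated correlation (adjusted p = 0.0774 and 0.109). In all, 8833 genes (64.0% of those tested) were called, 4440 higher and 4393 lower, and 705 rose and 1188 fell by at least 2-fold. All 4 libraries of one group lay above all 4 of the other for 8103 genes (58.7%), where chance gives 2.86%. Of the 95 called genes that the naming rule picked, 91 had their groups apart in this way. Part of the rule required it, so this share is no further evidence. Scaling by library totals alone moved the median log2 fold change of all genes from -0.01 to -0.155 and the share of calls that were higher from 50.3% to 36.1%, so list medians near 0 have no direction of their own, while those of the 15 lists called in this comparison kept their sign.

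All 32 genes of the G2/M and mitosis list fell (32 adjusted over the list alone), with a median log2 fold change of -4.26 (camera adjusted p = 7.02e-150). KIF20A, a kinesin of cytokinesis, fell from 169 ± 1.98 to 3.59 ± 0.692 CPM, and TOP2A, the topoisomerase that doxorubicin poisons, fell from 559 ± 35.4 to 30.2 ± 1.44 CPM. CCNB1, the mitotic cyclin B1, fell from 139 ± 6.82 to 11.9 ± 1.3 CPM. Of 34 DNA replication genes, 33 fell and 1 did not pass (33 adjusted over the list alone), with a median of -2.72 (camera adjusted p = 6.45e-85). RRM2, a subunit of the enzyme that makes deoxyribonucleotides, fell from 384 ± 4.06 to 32.3 ± 1.43 CPM, and MCM7, part of the replicative helicase, fell from 325 ± 12.4 to 33.2 ± 1.51 CPM. Of 27 DNA repair genes, 24 fell, 1 rose and 2 did not pass (24 and 1 adjusted over the list alone), with a median of -2.72 (camera adjusted p = 1.07e-22). FANCD2, of the pathway that repairs DNA crosslinks, fell from 48.7 ± 3.49 to 3.92 ± 0.655 CPM. The gene that rose, ATR, a kinase that senses stalled replication and was singled out after its values were seen, went from 51.0 ± 4.01 to 60.0 ± 4.71 CPM and was not called higher with library totals alone. Outside the lists, NEURL1B, a ubiquitin ligase gene, had the largest fall under the naming rule, from 28.4 ± 1.22 to 0.585 ± 0.266 CPM.

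Single genes of the response to DNA damage rose. MDM2, a ubiquitin ligase, rose from 84.2 ± 5.49 to 213 ± 13.1 CPM (1.34 ± 0.057, adjusted p = 3.33e-11). ZMAT3, an RNA-binding tumour suppressor, rose from 85.6 ± 6.25 to 314 ± 8.89 CPM, and TNFRSF10B, a death receptor, from 116 ± 1.24 to 269 ± 6.07 CPM. GDF15, a secreted stress factor among the 16 anchor genes, had 0 to 7 counts per library and was not tested. Of 31 apoptosis genes, 13 rose, 7 fell and 11 did not pass (camera adjusted p = 0.508), and their median of 0.05 turned negative with library totals alone.

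Of 33 replication-dependent histone genes, whose mRNAs lack a poly(A) tail, 8 were tested, 6 of them rose and 2 did not pass (6 adjusted over the list alone). Their median was 1.88 (camera adjusted p = 0.0178), with an adjusted p = 0.0774 with an estimated correlation. H1-2, a linker histone gene, rose from 6.39 ± 0.727 to 23.5 ± 1.83 CPM, and H4C8 rose from 0.678 ± 0.177 to 9.64 ± 1.13 CPM. Outside the list, the core histone genes H2AC6 and H2BC21 rose from 4.28 ± 0.595 to 38.6 ± 1.78 CPM and from 1.88 ± 0.501 to 19.8 ± 0.511 CPM. The members not tested had at most 11 counts in any library or no place in the table. Whether the libraries were made from RNA with poly(A) tails is not stated in the labels, and with no filter on low counts 5 histone genes at low counts, H3C3, H2AC14, H2AC17, H2AC20 and H3C15, named after their values were seen, were called lower. H2AC20, also outside the list, had 15 to 29 counts per control library, which the main filter does not remove, and 1 to 5 per doxorubicin library. Its log2 fold change in the unfiltered fit was -3.05 (edgeR adjusted p = 0.000263).

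**Figure D2:**
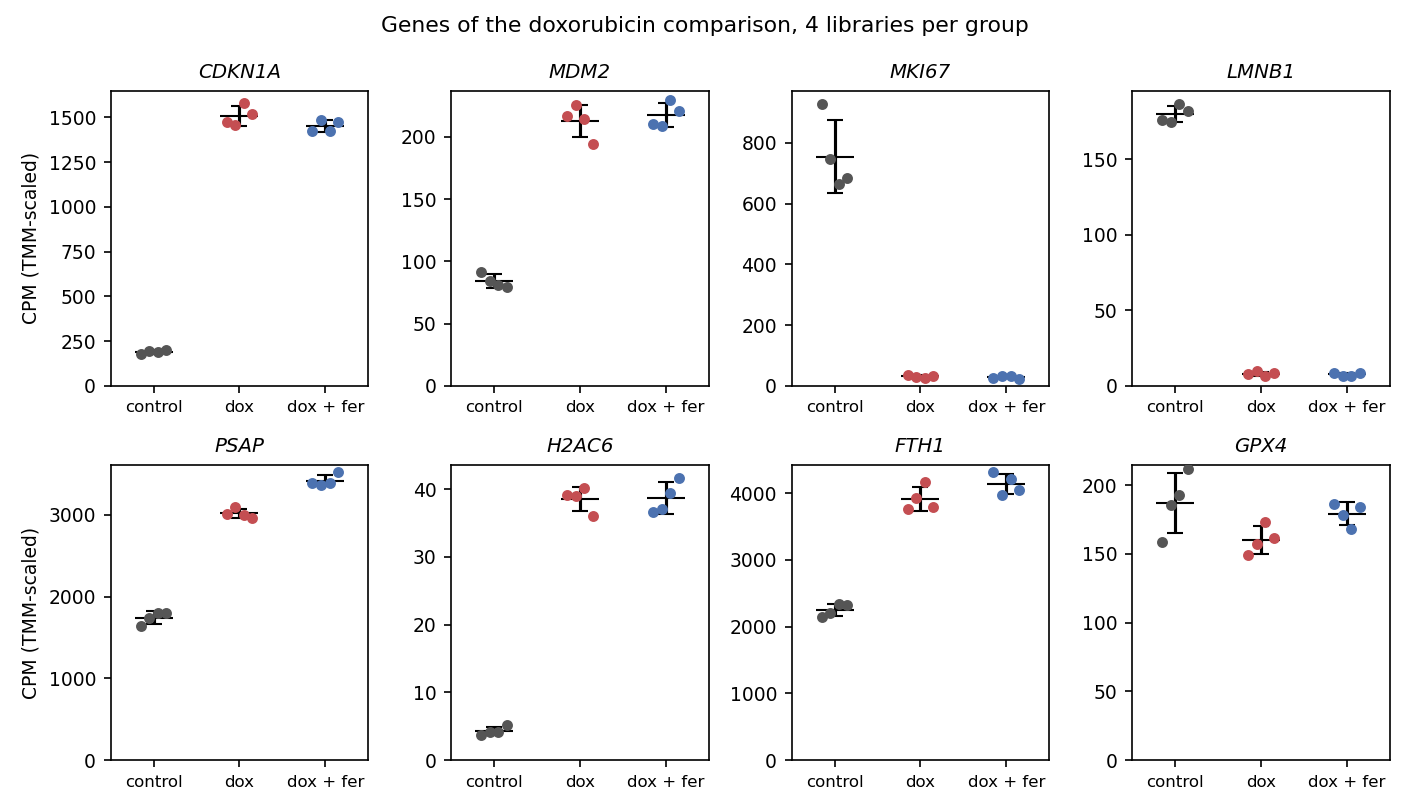
Levels in CPM of 8 genes in the 12 libraries, 1 point per library, with the mean and SD of each group (n = 4) and axes from 0. CDKN1A, MDM2, PSAP, H2AC6 and FTH1 were higher and MKI67 and LMNB1 lower in both treated groups than in control, while the 3 groups of GPX4 points overlap.

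Of 23 tested factors of the senescence-associated secretory phenotype (SASP), 16 rose, 3 fell and 4 did not pass (17 and 3 adjusted over the list alone), with a median of 0.71 (camera adjusted p = 7.28e-13). PLAT, tissue plasminogen activator, rose from 64.5 ± 1.41 to 264 ± 6.83 CPM, and IGFBP3, which binds insulin-like growth factors, from 117 ± 5.62 to 499 ± 27.4 CPM. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose from 2.89 ± 0.860 to 36.4 ± 2.16 CPM. The 3 that fell were VEGFA, IGFBP4 and AREG, named after their values were seen. CXCL8, an inflammatory chemokine named after its values were seen, had at most 5 counts in any library and was not tested. NF-kB targets went both ways, with 5 of 17 higher (NFKBIE, NFKB2, RELB, TNIP1 and CYLD, named after their values were seen), 7 lower and 5 not passed (5 and 8 adjusted over the list alone, camera adjusted p = 0.985). Of 22 interferon-stimulated genes, 7 rose, 8 fell and 7 did not pass (camera adjusted p = 0.985).

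Matrix and contractile genes also rose. Of 22 extracellular matrix genes, 15 rose, 4 fell (COL1A1, COL6A3, COL12A1 and TNC) and 3 did not pass. Their median was 0.80 (camera adjusted p = 6.17e-09), with an adjusted p = 0.109 with an estimated correlation. COL4A1, a basement membrane collagen, rose from 245 ± 5.79 to 746 ± 32.0 CPM. Of 23 actin cytoskeleton genes, 17 rose, 3 fell (TAGLN2, TPM4 and MYH10) and 3 did not pass (median 0.37, camera adjusted p = 2.14e-06), and ACTA2, smooth muscle actin, rose from 31.4 ± 1.15 to 134 ± 8.43 CPM. Of 21 TGF-beta targets, 11 rose, 8 fell and 2 did not pass (median 0.17, camera adjusted p = 6.32e-07), and CCN2, a matricellular growth factor gene, rose from 406 ± 18.7 to 1429.5 ± 57.6 CPM. Of 22 YAP/TAZ targets, 15 rose, 4 fell (AJUBA, AXL, FOXF2 and GADD45B) and 3 did not pass (median 0.36, camera adjusted p = 2.87e-05), and ANKRD1, a cofactor gene raised by YAP, rose from 557 ± 26.6 to 1481 ± 60.3 CPM. The members of these lists that fell are named after their values were seen. The lists share members such as CCN2 and ACTA2, so their tests are not independent.

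Lysosomal, mitochondrial and ribosomal transcripts rose in share. Of 30 lysosome genes, 25 rose, 3 fell (CTSL, CTSS and NPC1, named after their values were seen) and 2 did not pass (median 0.61, camera adjusted p = 1.95e-09). GAA, lysosomal alpha-glucosidase, rose from 30.3 ± 1.90 to 86.2 ± 1.96 CPM, and PSAP, the precursor of the saposins, from 1742 ± 75.6 to 3015 ± 59.7 CPM. All 13 mitochondrially encoded genes rose (12 with library totals alone), with a median of 0.56 (camera adjusted p = 0.00012, and an adjusted p = 0.296 with an estimated correlation). MT-CO1, cytochrome c oxidase subunit I, rose from 8392 ± 234 to 14441 ± 229 CPM. Of 31 nuclear genes of oxidative phosphorylation, 13 rose, 3 fell (NDUFA9, SDHA and UQCRC1, named after their values were seen) and 15 did not pass (camera adjusted p = 0.405), while with library totals alone 5 rose and 9 fell. Of 32 cytosolic ribosomal protein genes, 28 rose and 4 did not pass (17 rose with library totals alone), with a median of 0.30 (camera adjusted p = 0.00793, and an adjusted p = 0.736 with an estimated correlation).

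Genes of the ferroptosis pathway moved in both directions after doxorubicin. Camera called neither the defence nor the ferroptosis-promoting list. Fry, which called 32 of 35 lists in this comparison, called both higher (adjusted p = 0.00955 and 3.3e-05). Of 24 defence genes, 11 rose, 10 fell and 3 did not pass (12 and 10 adjusted over the list alone, camera adjusted p = 0.509), with a median of 0.08 and a mean of -0.05. SLC7A11, the cystine importer (chromosome 4 from 138164097 to 138242349), rose from 67.4 ± 3.92 to 106 ± 4.59 CPM (0.66 ± 0.077, adjusted p = 2.81e-06), and TXNRD1, a thioredoxin reductase, from 661 ± 17.4 to 1604 ± 68.1 CPM. GPX4, which reduces lipid peroxides (chromosome 19 from 1103926 to 1106791), fell from 187 ± 22.0 to 160 ± 10.1 CPM (-0.22 ± 0.074, adjusted p = 0.0153), a call lost without control replicate 4 (adjusted p = 0.0539). COQ2, an enzyme of coenzyme Q synthesis, fell from 21.7 ± 1.48 to 8.02 ± 1.04 CPM. AIFM2, the coenzyme Q reductase FSP1, had an adjusted p = 0.0204 for a fall by 0.20, lost without control replicate 3 (0.0596) or 4 (0.0597) or doxorubicin replicate 1 (0.0509) or 2 (0.0690). Of 19 ferroptosis-promoting genes, 6 rose, 6 fell and 7 did not pass (camera adjusted p = 0.509). CYB5R1, an oxidoreductase that drives lipid peroxidation, rose from 21.6 ± 0.878 to 64.6 ± 2.76 CPM. ACSL4, which loads polyunsaturated fatty acids into lipids, did not pass at 209 ± 8.97 and 224 ± 11.0 CPM (adjusted p = 0.101, called without control replicate 1, 0.0454, or doxorubicin replicate 4, 0.0357). PTGS2, a ferroptosis marker coding for cyclooxygenase 2, did not pass at 1.44 ± 0.0807 and 0.942 ± 0.171 CPM (adjusted p = 0.111).

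Iron handling genes were split as well, with 12 of 25 higher, 9 lower and 4 not passed (12 and 9 adjusted over the list alone, camera adjusted p = 0.359). Fry called this list higher (adjusted p = 5.48e-05). FTH1, the ferritin heavy chain that stores iron, rose from 2252 ± 93.8 to 3913 ± 184 CPM (0.80 ± 0.041, adjusted p = 2.58e-10). TFRC, the transferrin receptor, fell from 357 ± 13.4 to 303 ± 7.76 CPM (-0.24 ± 0.047, adjusted p = 0.000433). Targets of NRF2, the oxidant-response factor, rose, with 21 of 25 higher, 2 lower (GSR and UGDH, named after their values were seen) and 2 not passed (21 and 2 adjusted over the list alone). Their median was 0.64 (camera adjusted p = 3.02e-05), with an adjusted p = 0.192 with an estimated correlation. HMOX1, haem oxygenase 1, rose from 17.8 ± 0.664 to 27.8 ± 1.35 CPM. Of 24 cholesterol synthesis genes, 16 rose, 2 fell (EBP and INSIG1, named after their values were seen) and 6 did not pass (17 and 3 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 0.00658, and an adjusted p = 0.296 with an estimated correlation). With library totals alone, the medians of the ferroptosis defence, ferroptosis-promoting and iron lists all turned negative.

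The comparison of both compounds with doxorubicin alone asked what ferrostatin-1 changed in doxorubicin-treated cells. The clearest change was in targets of the aryl hydrocarbon receptor, a ligand-activated sensor of foreign aromatic compounds. Of 13 members, 7 were tested. Of these, 5 fell, 0 rose and 2 did not pass (5 adjusted over the list alone), with a median of -0.92 (camera adjusted p = 3.36e-88). CYP1A1, CYP1A2, ALDH3A1 and UGT1A6, named after their values were seen, had at most 10 counts in any library and were not tested. UGT1A1 and ASB2 had no place in the table. CYP1B1, a cytochrome P450 of xenobiotic metabolism (ENSG00000138061.12, chromosome 2 from 38066973 to 38109902), fell from 97.3 ± 5.08 to 10.8 ± 0.419 CPM (-3.17 ± 0.053, adjusted p = 3.47e-14) and was at 114 ± 2.92 CPM in control. TIPARP, an ADP-ribosyltransferase that feeds back on the receptor, fell from 116 ± 3.64 to 52.7 ± 0.850 CPM (-1.14 ± 0.043, adjusted p = 5.23e-10). AHRR, the receptor's repressor, fell from 28.3 ± 2.82 to 14.7 ± 1.48 CPM (-0.95 ± 0.080, adjusted p = 3.36e-06). SLC7A5, a large amino acid transporter, fell from 912 ± 32.6 to 480 ± 34.3 CPM (-0.92 ± 0.048, adjusted p = 2.30e-08). NFE2L2, which codes for NRF2 and was named after its values were seen, fell by 0.25 (adjusted p = 0.0334). When every library was thinned to the smallest total, it fell by 0.22 and was not called (adjusted p = 0.0640). In doxorubicin against control the same list had 3 of 7 higher (TIPARP, SLC7A5 and NQO1, a quinone reductase), 3 lower (CYP1B1, AHRR and NFE2L2) and 1 not passed (3 and 4 adjusted over the list alone, camera adjusted p = 0.557), with a negative median of -0.23 where the test pointed up.

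**Figure D3:**
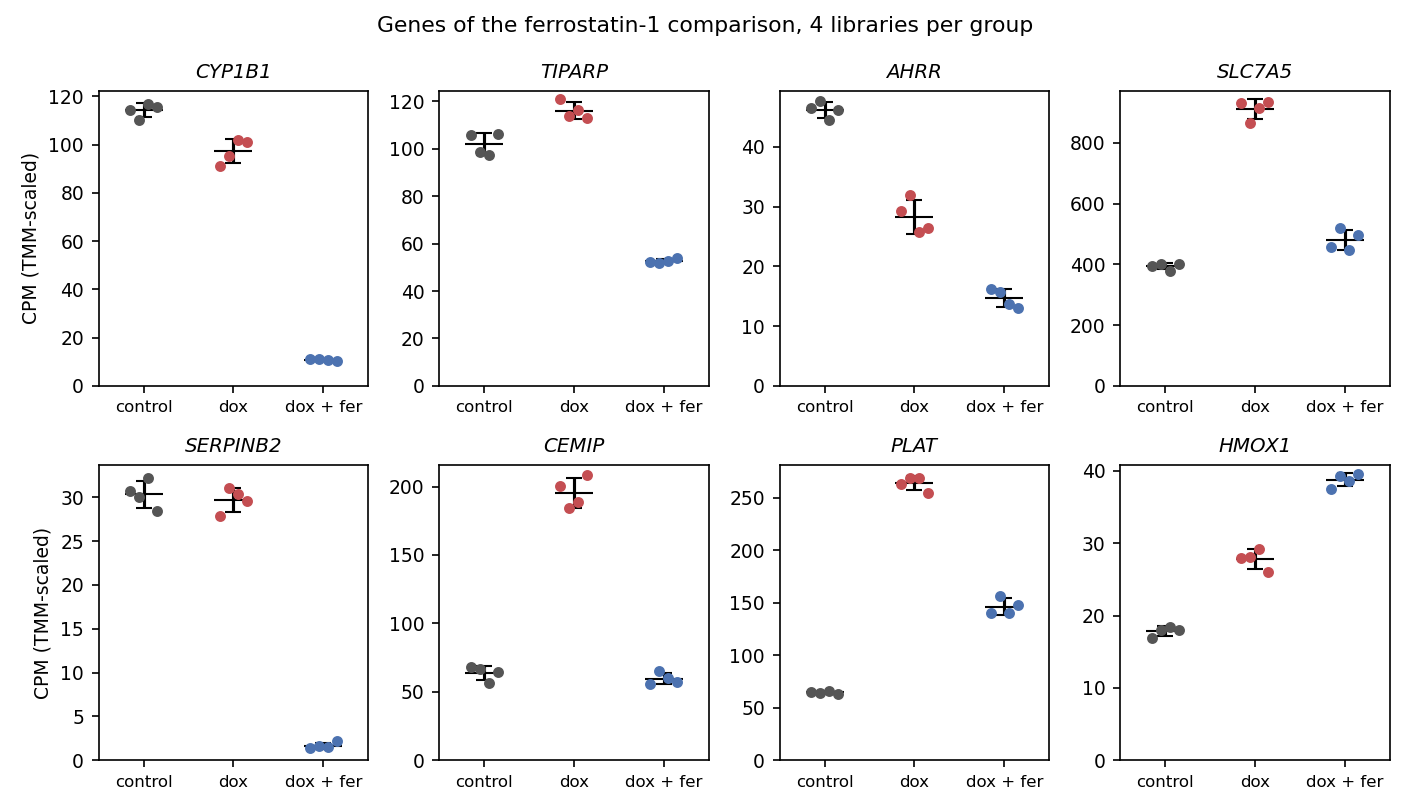
Levels in CPM of 8 genes in the 12 libraries, 1 point per library, with the mean and SD of each group (n = 4) and axes from 0. CYP1B1, TIPARP, AHRR, SLC7A5, SERPINB2, CEMIP and PLAT were lower and HMOX1 higher with both compounds than with doxorubicin alone.

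Ferrostatin-1 also lowered secreted factors. Of 23 SASP factors, 9 fell, 2 rose and 12 did not pass (14 and 2 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 2.26e-13). PLAT fell from 264 ± 6.83 to 146 ± 7.79 CPM (-0.85 ± 0.042, adjusted p = 1.34e-08), above its control level of 64.5 ± 1.41 CPM. CCL2, a monocyte-attracting chemokine, fell from 7.95 ± 1.96 to 2.10 ± 0.103 CPM, and IL1B, an inflammatory cytokine, from 7.53 ± 1.29 to 2.31 ± 0.469 CPM. FGF2, a growth factor, fell from 368 ± 13.5 to 256 ± 15 CPM. SERPINE2 and TIMP2 rose and were named after their values were seen. Of 17 NF-kB targets, 1 fell, TNFAIP2, named after its values were seen (camera adjusted p = 0.0517, called without doxorubicin replicate 3, 0.0256, or combined-treatment replicate 1, 0.0433, and with RLE size factors, 0.0488). Interferon-stimulated genes were not called as a list by camera (adjusted p = 0.148), with 19 of 22 not passed and 0 higher. Fry called the NF-kB (adjusted p = 0.00148) and interferon lists (0.00708) lower.

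Among single genes, SERPINB2, the plasminogen activator inhibitor PAI-2 (chromosome 18 from 63871692 to 63903890), had the largest fall under the naming rule. It fell from 29.7 ± 1.37 to 1.66 ± 0.331 CPM (-4.16 ± 0.10, adjusted p = 3.31e-12), against 30.3 ± 1.54 CPM in control. CEMIP, which degrades hyaluronan (chromosome 15 from 80779343 to 80951776), fell from 195 ± 10.9 to 59.5 ± 4.04 CPM (-1.72 ± 0.065, adjusted p = 5.23e-10), near its control level of 63.9 ± 5.23 CPM. SHISA2, a regulator of WNT and FGF receptors, fell from 17.1 ± 1.16 to 3.33 ± 0.176 CPM, and NPTX1, a secreted pentraxin, from 3.15 ± 0.754 to 0.397 ± 0.050 CPM. TMEM156, a membrane protein gene, fell from 6.26 ± 0.660 to 1.47 ± 0.321 CPM. Rises were smaller. FHL1, a LIM-domain protein of muscle, rose from 7.93 ± 1.19 to 15.6 ± 0.157 CPM, and RGS5, a pericyte regulator of G-protein signalling, from 16.4 ± 0.891 to 30.1 ± 2.96 CPM. The 8 largest rises also held LDAF1 and BDP1, whose symbols stand under several identifiers, and RPL36A-HNRNPH2, a readthrough of neighbouring genes. No fold is given for these, and LDAF1 lost its call without control replicates 2, 3 or 4, doxorubicin replicates 2 or 3 or combined-treatment replicates 1, 2 or 4 (adjusted p up to 0.134). In all, 692 genes (5.01%) were called, 298 higher and 394 lower, and 18 rose and 37 fell by at least 2-fold. Of those changed by at least 2-fold, 9 stood at identifiers that share their symbol with another. The 298 became 198 without doxorubicin replicate 1, 193 without doxorubicin replicate 2 and 191 without combined-treatment replicate 4. For 1503 genes (10.9%, against 2.86% by chance) the 4 libraries of each group were apart. They were also apart for 67 of the 71 called genes that the naming rule picked, part of which required it.

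The lists of contractile genes and TGF-beta targets were called higher with ferrostatin-1 than without it, while matrix genes were split. Of 21 TGF-beta targets, 9 rose, 1 fell and 11 did not pass (10 and 3 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 3.28e-06). ACTA2 rose from 134 ± 8.43 to 183 ± 12.3 CPM (0.45 ± 0.055, adjusted p = 0.000142), and SMAD6, an inhibitor of BMP signalling, rose from 18 ± 0.839 to 27.1 ± 2.33 CPM, below its control level of 34 ± 1.27 CPM. ITGA11, a collagen-binding integrin and the member that fell, went from 587 ± 32.8 to 382 ± 21.8 CPM. Of 23 actin cytoskeleton genes, 4 rose, ACTA2, TAGLN, TPM1 and TAGLN2, which had fallen after doxorubicin, and 19 did not pass (10 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 3.28e-06). Of 22 extracellular matrix genes, 3 rose (TGFBI, COL4A2 and, named after its values were seen, COL4A1), 6 fell and 13 did not pass (4 and 7 adjusted over the list alone), with a median of -0.08 (camera adjusted p = 0.0108, and an adjusted p = 0.487 with an estimated correlation). THBS1, the matrix glycoprotein thrombospondin 1, fell from 5703 ± 116 to 3392 ± 221 CPM (-0.75 ± 0.046, adjusted p = 1.13e-07). Of 22 YAP/TAZ targets, 1 rose (CCN2), 3 fell (AJUBA, F3 and IGFBP3) and 18 did not pass (1 and 6 adjusted over the list alone). Their median was -0.05 (camera adjusted p = 0.0140, and an adjusted p = 0.231 with an estimated correlation), a call lost without combined-treatment replicate 1 (0.0584).

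**Figure D4:**
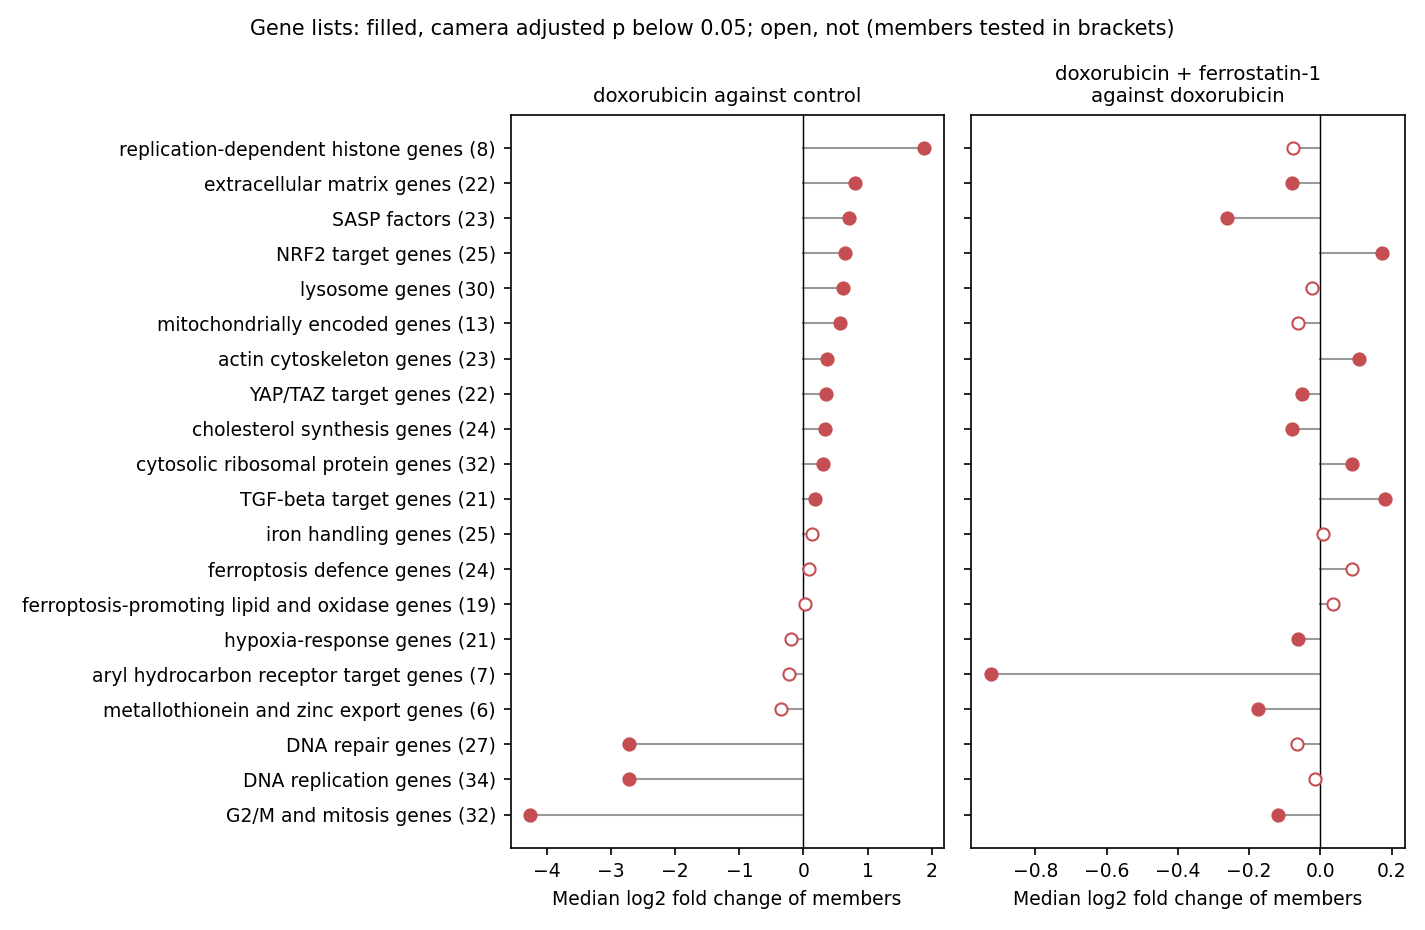
Median log2 fold change of the tested members of each gene list after doxorubicin (left) and after adding ferrostatin-1 to doxorubicin (right), for the reported lists called in either comparison and for the ferroptosis and iron lists, with filled points where the camera adjusted p was below 0.05. G2/M genes had a median of -4.26 after doxorubicin and aryl hydrocarbon receptor targets a median of -0.92 with ferrostatin-1, and with library totals alone the doxorubicin medians of the ferroptosis and iron lists turned negative.

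Most genes of ferroptosis and iron handling did not pass with ferrostatin-1. Over all tested genes 5.01% were called, and each of the ferroptosis and iron lists had a larger share. Of 24 ferroptosis defence genes, 1 rose, 2 fell and 21 did not pass (3 and 3 adjusted over the list alone, camera adjusted p = 0.380). SLC3A2, the partner of SLC7A11 and SLC7A5 in amino acid transport, fell from 299 ± 6.31 to 222 ± 20.4 CPM (-0.43 ± 0.068, adjusted p = 0.00145), and GCH1, which starts tetrahydrobiopterin synthesis, from 4.40 ± 0.429 to 2.46 ± 0.205 CPM. SCD, which makes monounsaturated fatty acids, rose from 567 ± 25.8 to 685 ± 43.8 CPM. GPX4 did not pass at 160 ± 10.1 and 179 ± 8.37 CPM (0.16 ± 0.074, adjusted p = 0.302), nor did SLC7A11 at 106 ± 4.59 and 121 ± 15.4 CPM (adjusted p = 0.235) or ACSL4 (adjusted p = 0.923). Of 19 ferroptosis-promoting genes, FADS2, a fatty acid desaturase, rose by 0.22 and PTGS2 fell from 0.942 ± 0.171 to 0.248 ± 0.164 CPM (2 and 1 adjusted over the list alone, camera adjusted p = 0.608). The median of this list was 0.03 and its mean -0.07. CHAC1, a glutathione-degrading enzyme, did not pass (adjusted p = 0.0600) but was called without combined-treatment replicate 3 (0.0256).

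Of 25 iron handling genes, HMOX1 rose from 27.8 ± 1.35 to 38.8 ± 0.919 CPM (0.48 ± 0.050, adjusted p = 2.73e-05) and FBXL5, an iron-sensing ubiquitin ligase subunit, fell from 69.1 ± 5.75 to 53.2 ± 3.38 CPM. ACO1, the iron regulatory protein IRP1, fell by 0.17 (adjusted p = 0.0174), a call lost without doxorubicin replicate 1 (0.0708) or combined-treatment replicate 1 (0.0624). The other 22 did not pass (1 and 5 adjusted over the list alone, camera adjusted p = 0.900), and the list's median of 0.01 and mean of -0.03 differ in sign. Of 25 NRF2 targets, 5 rose, 0 fell and 20 did not pass (10 and 1 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 6.56e-08, and an adjusted p = 0.166 with an estimated correlation). PGD, an NADPH-producing enzyme, rose from 239 ± 4.70 to 282 ± 7.05 CPM, and ABCC3, an export pump, from 7.01 ± 0.673 to 10.7 ± 1.44 CPM. The other 3 were HMOX1, TKT and UGDH, the last named after its values were seen. Of 29 ATF4 targets, the amino acid stress response, 5 rose (ASNS, PSAT1, PHGDH, CEBPG and GARS1), 3 fell (SLC7A5, SLC3A2 and STC2) and 21 did not pass (9 and 4 adjusted over the list alone, camera adjusted p = 0.762). Of these, all but SLC7A5 and SLC3A2 were named after their values were seen. Their median of 0.11 was positive where the test pointed down.

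With ferrostatin-1 added to doxorubicin, CDKN1A did not pass at 1508 ± 55.7 and 1452 ± 32.2 CPM (-0.05 ± 0.040, adjusted p = 0.589), nor did MKI67 at 31.3 ± 4.03 and 28.8 ± 4.31 CPM (adjusted p = 0.762). Of 32 G2/M genes, 3 fell (TPX2, MYBL2 and TOP2A) and 29 did not pass (3 adjusted over the list alone), with a median of -0.12 (camera adjusted p = 0.0427, and an adjusted p = 0.472 with an estimated correlation). The list's call was lost without doxorubicin replicate 2 (0.129) or 3 (0.0518) or combined-treatment replicate 4 (0.193). TPX2 lost its call without doxorubicin replicate 1 (0.0775) or 2 (0.0822) or combined-treatment replicate 1 (0.0698). MYBL2 lost it without doxorubicin replicates 1, 2 or 3 or combined-treatment replicates 1, 3 or 4 (up to 0.0980), and TOP2A without doxorubicin replicates 2, 3 or 4 or combined-treatment replicates 1 or 4 (up to 0.0984). Among other genes picked by the naming rule, KITLG, the ligand of KIT, rose from 32.9 ± 1.45 to 39.8 ± 2.40 CPM. RPS27L and AEN also rose. The call of RPS27L was lost without any 1 of doxorubicin replicates 1 to 4 or combined-treatment replicates 1, 3 and 4 (adjusted p up to 0.108), and that of AEN without any 1 of doxorubicin replicates 1 to 3 or combined-treatment replicates 1, 2 and 4 (up to 0.105). In the other growth lists, RRM2 was the 1 of 34 replication genes (camera adjusted p = 0.762) and RAD54B the 1 of 27 repair genes (camera adjusted p = 0.380) that fell, both named after their values were seen. None of the 8 tested histone genes passed by edgeR, 0 had an unadjusted p below 0.05, and 0 passed by DESeq2 or limma-voom (camera adjusted p = 0.760).

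Several other lists were called by camera in this comparison at the preset correlation but not with an estimated one. Fry called the cholesterol synthesis (adjusted p = 0.0120), hypoxia (0.00444) and metallothionein lists (0.00444) lower. It did not call the ribosomal list (0.251). Of 24 cholesterol synthesis genes, 4 fell, 0 rose and 20 did not pass (5 and 1 adjusted over the list alone), with a median of -0.08 (camera adjusted p = 0.00798, and an adjusted p = 0.340 with an estimated correlation). INSIG1, which holds back sterol synthesis, fell from 92.0 ± 3.70 to 69.2 ± 0.595 CPM (-0.41 ± 0.040, adjusted p = 1.43e-05), and ACAT2 and TM7SF2 fell by 0.23 and 0.30. The fourth, HMGCS1, lost its call without control replicates 2 or 3, doxorubicin replicates 1, 2 or 3 or combined-treatment replicates 1, 2 or 4 (adjusted p up to 0.129). Of 21 hypoxia-response genes, 5 fell (BNIP3L, VEGFA, LDHA, SLC2A1 and HK2), 1 rose (ENO2) and 15 did not pass (7 and 2 adjusted over the list alone), with a median of -0.06 (camera adjusted p = 0.0319, and an adjusted p = 0.264 with an estimated correlation). HK2 and ENO2 were named after their values were seen. The list's call was lost without doxorubicin replicate 3 (0.0614) or combined-treatment replicate 3 (0.0752). BNIP3L, a receptor for mitophagy, fell from 175 ± 9.87 to 128 ± 7.00 CPM, and VEGFA, the vascular growth factor, from 61.7 ± 4.07 to 45.3 ± 1.48 CPM. Of 6 tested genes of the list of metallothioneins and zinc export, 3 fell and 3 did not pass (camera adjusted p = 0.0206, an adjusted p = 0.231 with an estimated correlation, and 0.0508 without combined-treatment replicate 3). MT1E, a metal-binding protein gene, fell from 246 ± 7.27 to 195 ± 3.63 CPM. The others, MT2A and MT1X, lost their calls when single libraries were left out, MT2A without doxorubicin replicates 1 or 4 or combined-treatment replicates 3 or 4 (up to 0.0667). MT1X lost it without control replicate 3, doxorubicin replicates 1, 3 or 4 or any 1 combined-treatment replicate (up to 0.109). Of 32 ribosomal protein genes, 1 rose and 31 did not pass, with a median of 0.09 (camera adjusted p = 0.000135, and an adjusted p = 0.682 with an estimated correlation). It was RPS23, whose call was lost without doxorubicin replicates 1 or 2 or combined-treatment replicates 1 or 4 (up to 0.0799).

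The comparison of both compounds with control asked how far the doxorubicin response remained with ferrostatin-1. CDKN1A was at 1452 ± 32.2 CPM against 191 ± 9.91 in control (2.93 ± 0.044, adjusted p = 5.89e-16), and MKI67 at 28.8 ± 4.31 against 754 ± 120 CPM (-4.72 ± 0.13, adjusted p = 3.43e-13). All 32 G2/M genes were lower (32 adjusted over the list alone, median -4.30, camera adjusted p = 1.34e-149). Of 23 SASP factors, 15 were higher and 4 lower, VEGFA, IL1B, CCL2 and IGFBP4, the last 3 named after their values were seen (median 0.69, camera adjusted p = 7.76e-08). NRF2 targets had 21 of 25 higher and 0 lower (median 0.85, camera adjusted p = 9.68e-08, and an adjusted p = 0.0820 with an estimated correlation), and HMOX1 was at 38.8 ± 0.919 against 17.8 ± 0.664 CPM (1.12 ± 0.051, adjusted p = 7.05e-11). Aryl hydrocarbon receptor targets, not called after doxorubicin alone, were lower, with 4 of 7 lower (CYP1B1, TIPARP, AHRR and NFE2L2) and 2 higher, NQO1 and SLC7A5 (median -0.61, camera adjusted p = 0.000833). CYP1B1 was at 10.8 ± 0.419 against 114 ± 2.92 CPM (-3.40 ± 0.053, adjusted p = 7.85e-16). GPX4 did not pass (-0.06 ± 0.073, adjusted p = 0.479), and ACSL4 did not (0.12 ± 0.051, adjusted p = 0.0564) but was called without control replicate 1 (0.0261), doxorubicin replicate 4 (0.0448) or combined-treatment replicate 2 (0.0236).

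In this comparison 8873 genes (64.3%) were called, 4420 higher and 4453 lower, and 711 rose and 1212 fell by at least 2-fold. The groups were apart for 7965 genes (57.7%, against 2.86% by chance). All 96 called genes of the naming rule had their groups apart, which part of the rule required. Called lists numbered 17 of 35, 13 up and 4 down, and those lowered were the G2/M, replication, repair and aryl hydrocarbon receptor lists. Unfolded protein response genes, endoplasmic reticulum chaperones and their regulators, were called here, with 16 of 24 higher and 2 lower, PDIA4 and DERL3, named after their values were seen (18 and 2 adjusted over the list alone, median 0.29, camera adjusted p = 0.0415, and an adjusted p = 0.506 with an estimated correlation). That call was lost without control replicate 1 (0.0575) or combined-treatment replicate 4 (0.0571). DNAJB9, an endoplasmic reticulum chaperone, was at 24.2 ± 1.80 against 10.4 ± 0.668 CPM. Cholesterol synthesis genes had 15 of 24 higher and 3 lower, INSIG1, EBP and ACAT2, the last 2 named after their values were seen (camera adjusted p = 0.0469, and an adjusted p = 0.490 with an estimated correlation), a call lost without control replicates 1 (0.0825), 2 (0.0546) or 3 (0.0535) or combined-treatment replicate 4 (0.0539). Of genes called in both this and the doxorubicin comparison, 3974 were higher in both and 3918 lower in both, where independent calls would give 1422 and 1417. Across genes the log2 fold changes of both comparisons had r = 0.928, and r = 0.848 when each used its own 2 control libraries, while a simulation without any effect gave 0.493 from the shared controls.

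The last comparison asked how many doxorubicin changes ferrostatin-1 moved back toward control. Of the 8833 genes changed by doxorubicin, 287 (3.25%) were called in the opposite direction when ferrostatin-1 was added, 194 raised and then lowered and 93 lowered and then raised. CEMIP went from 63.9 ± 5.23 CPM in control to 195 ± 10.9 with doxorubicin and back to 59.5 ± 4.04 with both compounds, which is 107% of its doxorubicin change on the log2 scale. THBS1 moved back by 73.9%, SLC7A5 by 76.3%, COL5A2, a fibrillar collagen chain, by 61.8% and PLAT by 41.9%. The median over the 287 genes, which were selected for an opposite change, was 68.6%, and 189 moved back by more than 50%. A further 278 genes moved in the same direction in both comparisons, such as HMOX1 and ACTA2 upward and AHRR and SHISA2 downward, so 50.8% of the 565 genes called in both were opposite. The naming rule also picked ZBTB45P2, COMMD3-BMI1, TAP2, PARN, a second identifier of RPS18 and ENSG00000268173.3 here, for which no fold is given. ZBTB45P2, COMMD3-BMI1 and that RPS18 identifier had 0 counts in all 4 doxorubicin libraries, and TAP2, PARN and RPS18 are symbols of several identifiers each. The ferrostatin-1 calls of these genes, TAP2 excepted, were lost when single libraries were left out (adjusted p up to 0.126), and each of the 12 libraries decided at least 1 of them.

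**Figure D5:**
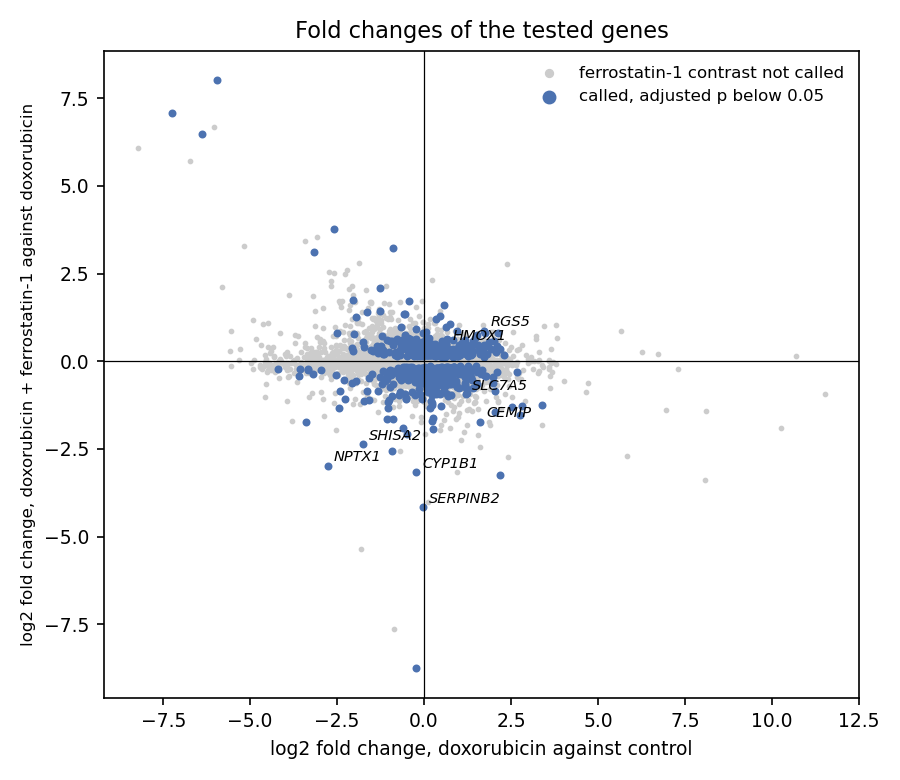
Log2 fold change with doxorubicin against control (horizontal) and with both compounds against doxorubicin alone (vertical), 1 point per tested gene, blue where the second comparison was called. Called genes lie in all 4 quadrants, and CYP1B1 and SERPINB2 fell with ferrostatin-1 with little change after doxorubicin.

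Both comparisons use the same doxorubicin libraries with opposite signs, which by itself gives a negative correlation of their fold changes. Across genes r was -0.17, against -0.135 in a simulation with the doxorubicin effect alone, and it was -0.04 when each comparison used its own 2 doxorubicin libraries. The slope over all genes was -0.0652, against -0.0364 in that simulation and -0.0166 in the splits. In those 6 splits, 87 to 131 genes were opposite, 49.6% to 55.5% of the genes called in both. Without combined-treatment replicate 1 the 287 genes became 191. If the calls of both comparisons were independent, 127 genes would be raised and then lowered (194 observed), 94.8 lowered and then raised (93 observed), 95.9 raised in both (155 observed) and 125 lowered in both (123 observed). PLAT, THBS1, CEMIP and SLC7A5 belong to the group raised and then lowered.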

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

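In this part, the draws from the SASP and NF-kB lists, the test for RNA without poly(A) tails, the overlap test with identifiers that have no symbol and the calls kept after summing by symbol were chosen only after the result was seen. Single libraries stood apart from the other 3 of their group for 20 genes and 1 summary value, by a gap between the library and its nearest neighbour that took more than the critical share of the group's range. That is 21 of 510 groups of 4 (4.12%), where chance gives about 5%. Control replicate 1 had 4 of them, control replicate 4 and combined-treatment replicates 3 and 4 had 3 each, and no library had more. No biological explanation of these values was tested, since replicates of a group were treated alike.

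Among genes named for doxorubicin, H2BC4 was at 0.794 CPM in control replicate 1 (0.212 to 0.293 in the others) and H2BC21 at 2.63 CPM in control replicate 4 (1.59 to 1.67). PSG4 was at 2.54 CPM in doxorubicin replicate 1 (4.48 to 4.79), IGFBP5 at 125 CPM in the same library (113 to 114), and H1-2 at 20.7 CPM in doxorubicin replicate 2 (24.0 to 24.7). NEK2 was at 1.82 CPM in combined-treatment replicate 4 (1.33 to 1.38) and MCM7 at 32.2 CPM in combined-treatment replicate 3 (35 to 35.5). HMGCS1 was at 58.7 CPM in control replicate 1 (55.4 to 55.9) and MT-CO1 at 8739 CPM in control replicate 1 (8230 to 8311). PSAP was at 3516 CPM in combined-treatment replicate 4 (3368 to 3392) and TGFBI at 564 CPM in combined-treatment replicate 1 (571 to 572). The doxorubicin calls of all these genes were kept whichever library was left out.

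Among genes named for ferrostatin-1 or for both compounds, TMEM156 was at 1.95 CPM in combined-treatment replicate 4 (1.28 to 1.33) and CCL2 at 5.81 CPM in control replicate 3 (6.85 to 7.04). RPS27L was at 91.9 CPM in control replicate 4 (88.2 to 88.4) and SLC3A2 at 159 CPM in control replicate 1 (188 to 192). COL4A2 was at 1471 CPM in combined-treatment replicate 2 (1277 to 1301), TAGLN2 at 923 CPM in combined-treatment replicate 3 (985 to 995) and DNAJB9 at 11.4 CPM in control replicate 3 (9.98 to 10.2). ENSG00000268173.3 was at 0.349 CPM in doxorubicin replicate 2 and at 0 in the other 3. The 10 most abundant genes took 7.90% of the counts in combined-treatment replicate 3 (7.68% to 7.71% in the others).

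Aryl hydrocarbon receptor targets fell with ferrostatin-1, with a median of -0.92 and 5 of 7 lower. A difference in library depth predicted fewer than 4 lower members once every library was thinned to 17523920 counts, and 4 remained. NFE2L2 was lost, though its log2 fold change was similar, -0.223 after thinning against -0.246 before. Totals ran only from 17523920 to 24879198 counts, so thinning could hardly remove the larger changes, and the depth test had little room to fail. The scaling of the libraries predicted fewer than 4 under some scaling, and the fewest over TMM, RLE, upper quartile and totals was 5. Mean TMM factors were close, 0.969 for doxorubicin and 0.964 for both compounds, so this test had little room to fail. A general fall of secreted-factor and NF-kB genes predicted medians as low in draws of as many genes from the 40 of both lists, whose own median was -0.16, and 0% of 10000 draws reached it. The receptor list had the lowest median of the lists tested in this comparison, and few genes of the 40 fell that far. These draws therefore also had little room to fail. A candidate explanation that stays open is lower receptor activity with ferrostatin-1, whether through the receptor or its ligands, and it cannot be tested here without a ferrostatin-1 group free of doxorubicin, nor parted from any handling that differed between the groups.

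Histone genes rose after doxorubicin while replication genes fell. Reads shared between near-identical histone genes predicted an equal sum, but the summed level of 59 histone genes was 46.3 ± 2.87 CPM in control and 205 ± 7.90 CPM with doxorubicin (SD, n = 4), a log2 ratio of 2.15 with all 4 doxorubicin libraries above all 4 controls (two-sided exact permutation p = 0.0286, the smallest this design allows). The rise therefore does not come from moving a fixed number of reads between copies. More RNA without poly(A) tails in the doxorubicin libraries stays open: with no filter on low counts 15 histone genes were called higher and 5 lower, but 0 of the lower ones reached 2 CPM in control, too few to decide. More poly(A)-tailed histone mRNA in arrested cells is a biological candidate explanation that was not tested.

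Some gene identifiers jumped between at most 5 and at least 100 counts among libraries of one group. Of 83 such identifiers, 65 (78.3%) had a symbol that stood under another identifier too, against 6.54% of the other tested identifiers (two-sided Fisher's exact test, p = 1.85e-59), and after summing over their 56 symbols 0 still jumped. A partner identifier with more than 5 counts in every library ends a jump by itself, so this 0 adds little. Of 8 jumping identifiers with a symbol of their own and a position, 5 (62.5%) overlapped another gene on the same strand, against 34.4% (Fisher's exact test, p = 0.134), too few to decide whether overlapping genes share reads. With 5 more that have no symbol, it was 9 of 13 against 35.1% (Fisher's exact test, p = 0.0165). TIGD5, chosen after its values were seen, is an example. Its counts lay on one identifier in 11 libraries and on both in doxorubicin replicate 4. Its summed level was 29.6 ± 3.06 CPM in control, 23.5 ± 1.88 with doxorubicin and 19.6 ± 1.45 with both compounds. These values are consistent with reads split between gene models that share a symbol. Identifiers that jumped held 13 calls of the doxorubicin and 0 of the ferrostatin-1 comparison. Calls at identifiers with a shared symbol, jumping or not, were 395 and 25, and 57 and 13 of them were lost when counts were summed by symbol, as were 8 of 14 such genes among the 287 moved back. BDP1 is an example, with a summed level of 41.2 ± 1.21 CPM with doxorubicin and 40.8 ± 4.10 with both compounds (adjusted p = 0.952).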

How the results depend on the processing

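In this part, the replicate block and the counts summed over identifiers with the same symbol were chosen only after the data were seen. No list and no named gene that could be compared reversed its direction as a called result under any alternative. With counts summed by symbol, 89 of 93 named ferrostatin-1 genes could be compared, and BDP1 was not among them. Its identifier was called higher with ferrostatin-1, but its summed counts had a log2 fold change of -0.0188 (edgeR adjusted p = 0.952). In other splits of the 8 libraries of each comparison into 4 and 4, fitted with edgeR, 1 of 35 splits, the real one, gave as many calls: 8745 for doxorubicin against at most 0 in another split, 651 for ferrostatin-1 against at most 3, and 8637 for both compounds against control against at most 2. The other splits mix libraries of both groups, so a real difference widens their spread and leaves few calls. With 35 splits, the real one standing alone is the strongest result this test could give. It cannot part the treatment from any handling that differed between the groups.

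Across tests, scalings, filters, gene sets and fits of only the 2 groups compared, calls numbered 7899 to 8998 for doxorubicin, 578 to 859 for ferrostatin-1 and 7949 to 9141 for both compounds against control. DESeq2 gave 859 ferrostatin-1 calls, limma-voom 682, and no filter on low counts 578. With the replicate block there were 8610, 502 and 8701 calls, and with counts summed by symbol 8956, 753 and 8970. Genes moved back by ferrostatin-1 numbered 207 with the block, 229 with no filter and 343 with DESeq2. With library totals alone the median of all genes was -0.155 for doxorubicin and -0.169 for both compounds, and 36.1% and 35% of calls were higher.

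Stricter thresholds shortened the counts by construction. At an adjusted p below 0.01, ferrostatin-1 changed 363 genes (137 higher, 226 lower) and 137 were moved back. With an absolute log2 fold change of at least 1, counts were 1893 (705 and 1188) for doxorubicin, 55 (18 and 37) for ferrostatin-1 and 1923 (711 and 1212) for both compounds, and 16 were moved back. Of the 55, 9 stood at identifiers that share their symbol with another. The 16 include the 6 identifiers with the largest opposite changes, for which no fold was given above. With doxorubicin libraries split 2 and 2 between the contrasts, 107 were moved back on average, with fewer libraries per contrast. With an estimated inter-gene correlation, 9, 4 and 9 lists were called in place of 15, 12 and 17. Fry, which asks a different question, called 32 for doxorubicin, 14 for ferrostatin-1 and 34 for both compounds.

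Leaving out 1 library gave 8407 to 8877 doxorubicin calls (4212 to 4431 higher, 4153 to 4453 lower) and 8471 to 8907 for both compounds (4179 to 4417 higher, 4292 to 4493 lower). For ferrostatin-1 it gave 491 to 786 (191 to 349 higher, 283 to 437 lower). The higher count was 198 without doxorubicin replicate 1, 193 without doxorubicin replicate 2 and 191 without combined-treatment replicate 4. Genes moved back numbered 191 to 317, with 191 without combined-treatment replicate 1. Called lists numbered 15 to 16, 11 to 14 and 15 to 17.

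Of the named genes, leaving out 1 library lost 14 and gained 2 of 1164 calls and non-calls for doxorubicin, lost 90 and gained 5 of 1116 for ferrostatin-1, and lost 0 and gained 3 of 1176 for both compounds. The block lost 13 of 93 ferrostatin-1 genes, fits of only the 2 groups compared lost 6, limma-voom 5 and DESeq2 1, with 6 gained by DESeq2. With library totals alone, both compounds against control lost 2 of 17 lists, the unfolded protein response (adjusted p = 0.109) and cholesterol synthesis (0.143), and the block lost cholesterol synthesis (0.0526). The cause of these changes was not tested. Depth limits low levels: 3 counts are 0.121 to 0.171 CPM, so genes such as NPTX1 and PTGS2 with both compounds lie within a few counts of that limit.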

Other observations

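In this part, the list from the side column was chosen only after the data were seen. Several lists went both ways after doxorubicin and were not called by camera, while fry called 32 of 35 lists in this comparison. Senescence markers had 10 of 23 higher, 10 lower and 3 not passed (camera adjusted p = 0.508), with CDKN1A among the higher and LMNB1 among the lower, and a median of 0.07 beside a mean of -0.24. Targets of ATF4 had 9 of 29 higher, 15 lower and 5 not passed (median -0.25, camera adjusted p = 0.509), and SESN2, a leucine sensor, rose from 14.7 ± 0.526 to 42.7 ± 1.40 CPM. Unfolded protein response genes had 14 of 24 higher, 2 lower (PDIA4 and DERL3, named after their values were seen) and 8 not passed (15 and 2 adjusted over the list alone, camera adjusted p = 0.0636, called without doxorubicin replicate 4, 0.0428). Fatty acid synthesis genes had 11 of 23 higher, 7 lower and 5 not passed (camera adjusted p = 0.508), and hypoxia-response genes 7 of 21 higher, 11 lower and 3 not passed (camera adjusted p = 0.626). The list of metallothioneins and zinc export had 1 of 6 higher (SLC30A1, a zinc exporter) and 4 lower (MT1E, MT1M, MT1X and MT2A), named after their values were seen (camera adjusted p = 0.555). Immediate early genes had 7 of 24 higher and 4 lower, FOSL1, EGR1, EGR3 and KLF6, named after their values were seen (camera adjusted p = 0.260) and heat shock genes 9 of 18 higher and 7 lower (camera adjusted p = 0.294). With library totals alone, the medians of the senescence, immediate early and heat shock lists turned negative.

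With ferrostatin-1, camera called none of the lists in this paragraph, and fry called the senescence list lower (adjusted p = 0.00444). Over all tested genes 5.01% were called. The hypoxia and metallothionein lists, called by camera with ferrostatin-1, are described above. Senescence markers had 2 of 23 higher (CDKN2B and HMGA1) and 3 lower (CDKN1B, NTN4 and PTPRJ), with a camera adjusted p = 0.121, and apoptosis genes 1 higher (BCL2L1) and 1 lower (BMF) of 31 (0.558). Fatty acid synthesis genes had 3 of 23 higher (SCD, SCD5 and FADS2) and 1 lower (PNPLA3), with 0.214, and lysosome genes 3 of 30 higher (CTSD, NPC1 and PSAP) and 1 lower (ASAH1), with 0.748. Of 13 mitochondrially encoded genes 1 rose (MT-ND6) and 2 fell (MT-CO3 and MT-ATP6), with 0.168 and 0.0143 without combined-treatment replicate 3, and MT-ND6 was not called with library totals alone. Immediate early genes had 2 of 24 lower (FOSL1 and IER3), with 0.188 and 0.0452 without combined-treatment replicate 2. Heat shock genes had 1 of 18 higher (CRYAB), with 0.0674 and 0.0363 without that library. None of 24 unfolded protein response genes or 31 nuclear oxidative phosphorylation genes passed by edgeR, with 1 and 2 at an unadjusted p below 0.05 and 0 by DESeq2 or limma-voom (0.448 and 0.333). All genes named in this paragraph other than SCD and FADS2 were chosen after their values were seen.

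Marker lists of cell types were few in tested members, since RPE1 cells express few of them. Retinal pigment epithelium markers had 1 of 11 higher after doxorubicin (RDH5) and 4 lower (OTX2, SLC6A15, MERTK and PAX6), with a camera adjusted p = 0.626, and 2 higher with ferrostatin-1 (MITF and RDH5), with 0.200. Epithelial markers had 4 of 8 higher (KRT7, KRT8, KRT18 and CLDN1) and 2 lower (CLDN4 and TJP1) after doxorubicin (0.260) and none called with ferrostatin-1 (2 at an unadjusted p below 0.05, 0 by DESeq2 or limma-voom, 0.702). Endothelial markers had 2 of 6 higher (TEK and EGFL7) and 1 lower (KDR) after doxorubicin (0.985) and none called with ferrostatin-1 (0 at an unadjusted p below 0.05, 0 by DESeq2 or limma-voom, 0.748). Neuronal markers had 2 of 6 higher (TUBB3 and GAD1) after doxorubicin (0.843), and with ferrostatin-1 TUBB3 rose and SYT1 fell (0.748). Only 3 immune markers had counts enough to be tested, so the list was not: CD68, a lysosomal glycoprotein, rose from 64.1 ± 3.77 to 73.7 ± 3.43 CPM, CSF1R, a growth factor receptor, fell from 3.42 ± 0.544 to 1.19 ± 0.507 CPM, and LYZ did not pass. With ferrostatin-1 none of the 3 was called (1 at an unadjusted p below 0.05, 0 by DESeq2 or limma-voom). All genes named in this paragraph were chosen after their values were seen. A side column of the deposited table holds 71 gene symbols of unstated purpose, of which 63 were tested. After doxorubicin 26 were higher and 20 lower (camera adjusted p = 0.560), and with ferrostatin-1 1 was higher and 2 were lower (0.488). If the study chose them on these libraries, they are no independent evidence.

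One hypothesis was that doxorubicin, which traps topoisomerases along transcribed DNA, lowered genes with a long genomic span. It predicted a partial rank correlation across genes of log2 fold change with span below -0.1, with exonic length, GC content and mean expression held fixed. Over 12462 protein-coding genes outside the cell division, replication and repair lists it was 0.0431, on the other side of 0, and the plain rank correlation was -0.0260. Genes are not independent replicates, so no p is given, and these values do not bear the hypothesis out.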
